A study of Mus musculus with 16 samples.

How the data were processed

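RNA was measured in 16 libraries of mouse retina (strain C57BL/6), 2 for each of 8 groups given by age (P1, P7, P14 and P30) and genotype label (control or Uxt CKO). Per the submitters' processing notes and labels, libraries were made from polyA+ RNA, sequenced as paired reads of 150 bp on an Illumina HiSeq instrument, aligned with HISAT2 to mm10 and counted with HTSeq. Versions, annotation release, strand setting and read filters are not given. The deposited values are raw read counts per Ensembl gene identifier, whole numbers with a different total in every library, and no normalization by the authors was found in them.

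The files hold 54532 gene identifiers, of which 54409 have a symbol in GENCODE M21, the source of the coordinates used here. Total counts ranged from 15807152 to 22815404 per library. On the TMM-scaled sizes 3 counts, the limit that a count of 0 allows, corresponded to between 0.138 and 0.202 CPM. Such limits and the counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

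Genes with too few counts were removed by edgeR's filterByExpr with the 8 groups, which left 21115. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) was fitted to all 16 libraries with 8 group means and 8 residual degrees of freedom. The common biological coefficient of variation was 0.0635. Each age compared the libraries labelled CKO with the controls of that age, interaction contrasts compared these differences between successive ages, and further contrasts compared controls of successive ages. P-values are from the edgeR quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all tested genes of a contrast at 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Groups of 2 allow neither tests for outlying samples, nor counts over other splits of the samples, nor correlations across samples within a group.

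In all, 35 gene lists with 457 genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists with at least 3 tested members. They cover retinal neurons and glia, immune cells, progenitors, proliferation, stress and death responses, chaperones, splicing, energy metabolism and other tissues of the eye. Each list was also tested with an estimated correlation and with fry, and counts of members were also adjusted over the list alone. The symbol Aldoa names 2 gene identifiers, so the glycolysis list holds 13 tested genes. The groups, contrasts, tests, filters, gene lists, naming rule and all but 2 alternative settings were chosen before the data were examined. After seeing the data, 7 lists of other tissues or functions were added, without a set test.

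Genes were named by rule. At each age Uxt was named, and then, among genes with an adjusted p under the threshold, a log2 fold change of at least 1 in size, at least 5 CPM in the higher group, both libraries labelled CKO on the same side of both controls, and a name other than that of a predicted gene, the 6 with the largest rise and the 6 with the largest fall. For up to 6 lists with the smallest camera adjusted p, the 2 called members with the smallest p in the list's direction were added. For each difference between successive ages the 3 largest in each direction were named by the same filters without the rule on sides. For control maturation 6 genes were fixed, of which Crx, Grm6, Glul, Mki67 and Pou4f2 are reported. Results that need genes withheld for evaluation are not reported. Xist and Y-linked genes served as a check of sex, and Abcd4, Zfp949, Cryaa, Col1a1, Scd1, Krt12, Bpifa6, Elovl5, Fasn, Plin2, Pax6, Tfap2a, Tfap2b, the genes called at all ages and the members of the added lists were named after their values were seen.

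The pipeline was tested on simulated data with 200 changed genes per age. At P1, P7, P14 and P30, 4-fold changes were recovered in 98.5%, 100%, 97.0% and 98.5% of cases. In the same order, 2-fold changes were recovered in 77.6%, 91.0%, 77.6% and 83.6%, and 1.5-fold changes in 56.7%, 73.1%, 73.1% and 59.7%. False calls made up 6.63%, 7.37%, 4.62% and 6.40% of the calls. The simulation gave a gene the same dispersion in all groups. Its rates need not hold at P14 and P30, where 12300 and 11874 genes were called in the data. Replicates of the P30 libraries labelled CKO also differed more than those of the other groups. Alternatives tried were RLE size factors, library size alone, no filter on low counts, a filter of at least 5 CPM in at least 2 libraries, a block for the replicate number, a covariate of Y-linked expression, each library left out in turn, each age fitted alone, DESeq2 1.42.0, and the other set tests. Scaling on the 49 genes of the bipolar, amacrine, horizontal and ganglion cell lists, and a fit without the P30 libraries, were added after seeing the data. No library was left out of the fit that gives the reported values.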

Results

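RNA was sequenced from mouse retina at postnatal days 1, 7, 14 and 30 (P1, P7, P14 and P30), in controls and in animals labelled as conditional knockouts (CKO) of Uxt, which encodes a prefoldin-like chaperone protein. In the knockout design, a Cre recombinase removes exon 3 of Uxt. Each age and genotype label held 2 libraries, 16 in all, with total counts between 15807152 and 22815404 and between 25614 and 27841 genes detected. The labels do not say that the libraries come from separate animals, so the p-values measure the spread between these samples, which may be technical. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom between 1.52 and 1.75 in the groups of P1 to P14, 4.71 in the P30 controls and 34.8 in the P30 libraries labelled CKO. Values are log2 fold changes of the libraries labelled CKO over the controls of the same age ± SE of the fit (n = 2 libraries per group), or counts scaled to the size of the library (CPM) ± SD (n = 2).

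Genes of tissues next to the retina were abundant. Cryaa, a lens crystallin, had the highest level of all genes in both groups at P1, P7 and P14, with 11429 ± 228 CPM in the P1 controls and 21775 ± 238 CPM in the P14 controls. Col1a1, a collagen of connective tissue, stood at 6686 ± 17.2 CPM in the P1 controls and 279 ± 17.3 CPM in the P30 controls. Crystallin genes took 9.65% and 9.80% of the counts in the P14 controls against 6.68% and 6.56% in the P14 libraries labelled CKO. Mitochondrially encoded genes took 2.40% and 2.56% in the P30 controls against 4.33% and 6.35% in the P30 libraries labelled CKO. Xist, transcribed from the inactive X chromosome of females, was at 1.12 ± 1.12 CPM in the P1 controls and 1454 ± 6.33 CPM in the P1 libraries labelled CKO, and at 2.13 ± 0.45 against 1370 ± 4.77 CPM at P7. The Y-linked Ddx3y ran the other way, at 76.4 ± 0.77 CPM in the P1 controls and 0 in both P1 libraries labelled CKO, where 3 counts would give at most 0.173 CPM. The groups of P1 and P7 therefore differ in sex as well as in label. The groups of P14 were both high in Xist (1202 and 810 CPM) and those of P30 both high in Ddx3y (79.1 and 83.6 CPM).

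Uxt itself was lower in the libraries labelled CKO at P1 and was not lower at the later ages. Uxt (ENSMUSG00000001134, chromosome X, 20941722 to 20962017, mm10) fell at P1 by 0.81 on the log2 scale (SE 0.19, adjusted p = 0.00728), from 7.40 ± 0.91 to 4.19 ± 0.88 CPM. Its log2 fold change was 0.23 ± 0.18 at P7 (adjusted p = 0.548) and 0.31 ± 0.18 at P14 (adjusted p = 0.155). At P30 it rose by 0.52 ± 0.19 (adjusted p = 0.0247), from 4.68 ± 0.33 to 6.73 ± 0.40 CPM. Uxt was thus not called at P7 and P14 and was higher at P30 in the libraries labelled CKO. Every direction given for P7, P14 and P30 is therefore a direction between labels. Exon 3 makes up 82 of the 875 nucleotides of the transcript, and the deposited counts are per gene, so they include transcripts that lack this exon. Uxt rested on 62 to 156 counts per library. The P1 call was lost without control replicate 2 (adjusted p = 0.0878) or without CKO replicate 2 (adjusted p = 0.117). The P30 call was lost without control replicate 2 (adjusted p = 0.0947), and a P14 call appeared without control replicate 2 (0.62, adjusted p = 0.0211).

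A second gene separated the labels at P1, P7 and P30 but not at P14. Abcd4 (ENSMUSG00000021240, chromosome 12, 84601464 to 84617413), which encodes a lysosomal vitamin B12 transporter, stood at 23.0 ± 0.01 CPM in the P1 controls and 153 ± 2.89 CPM in the P1 libraries labelled CKO, at 22.9 ± 1.92 and 138 ± 1.51 CPM at P7, and at 29.2 ± 0.84 and 100 ± 20.1 CPM at P30. At P14 the controls stood at 192 and 197 CPM and the libraries labelled CKO at 196 and 201 CPM (0.03 ± 0.09, adjusted p = 0.791). High Abcd4 went with high Xist at P1, P7 and P14 and with the label at P1, P7 and P30. At P30 both groups were low in Xist. Abcd4 was chosen at P1, P14 and P30 after its values were seen, and the naming rule picked it at P7 alone.

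**Figure D1:**
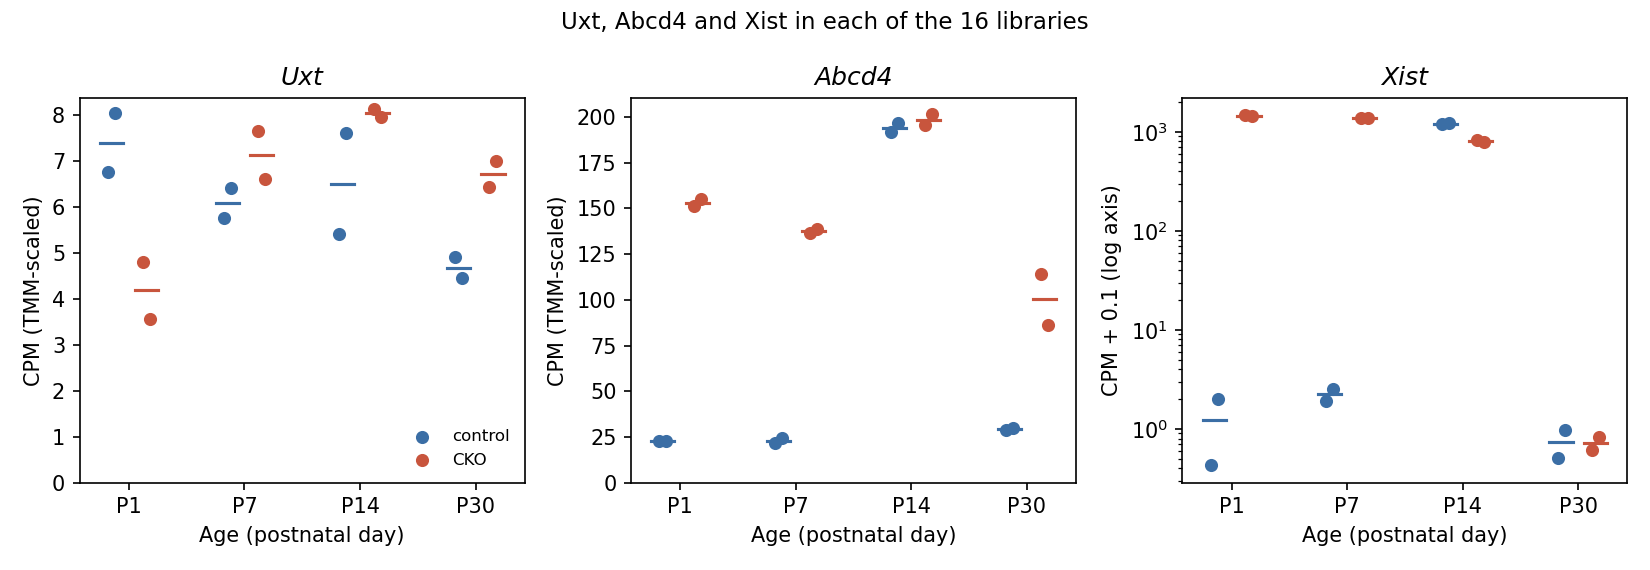
Uxt, Abcd4 and Xist in each of the 16 libraries, with age in postnatal days on the horizontal axis and CPM on the vertical axis (log axis with 0.1 added for Xist). Each point is 1 library and each bar the mean of 2. Abcd4 lies between 192 and 197 CPM in the P14 controls against at most 29.8 CPM in the other controls.

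The comparison at P1 asks what differs in newborn retina between the label CKO and control. Genes of young photoreceptors and of neurogenic precursors were lower in the libraries labelled CKO, while genes of microglia and targets of p53 were higher. Crx, a transcription factor of photoreceptors, fell from 158 ± 0.87 to 91.6 ± 0.39 CPM (-0.79 ± 0.04, adjusted p = 5.77e-10). Nr2e3, a transcription factor of rods, fell by 0.99 (SE 0.05, adjusted p = 5.77e-10). Neurod1 and Neurog2, proneural transcription factors, fell by 0.74 (SE 0.08, adjusted p = 8.49e-06) and 0.66 (SE 0.08, adjusted p = 2.98e-05). Among the complement genes of microglia, C1qc rose by 1.03 ± 0.07 (adjusted p = 3.71e-08). Pmaip1, a p53 target that promotes cell death, rose by 2.52 ± 0.26 (adjusted p = 3.35e-06). At P1, 2677 of 21115 genes passed an adjusted p of 0.05, 1290 higher and 1387 lower, and 329 of these changed at least 2-fold.

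Across the rod list at P1, 8 of 17 genes fell and 1 rose over all genes tested, and 10 fell and 1 rose adjusted over the list alone, with a median of -0.50 (camera adjusted p = 4.49e-13). Sag, the rod arrestin, fell by 1.40 (SE 0.09, adjusted p = 4.34e-09). In the list of genes common to rods and cones, 10 of 16 fell (1 rose and 11 fell adjusted over the list alone), with a median of -0.62 (camera adjusted p = 2.11e-14). Pdc, the photoreceptor phosducin, fell by 0.87 (SE 0.07, adjusted p = 2.45e-07). Of 13 cone genes 6 fell by either adjustment (median -0.48, camera adjusted p = 3.49e-05, adjusted p = 0.175 with an estimated correlation). Photoreceptor synapse genes fell in 7 of 11 cases (1 rose and 8 fell adjusted over the list alone, median -0.33, camera adjusted p = 1.45e-05, adjusted p = 0.0829 with an estimated correlation). Cilium genes fell in 6 of 16 cases (8 adjusted over the list alone, median -0.19, camera adjusted p = 0.00109, adjusted p = 0.3 with an estimated correlation). Amacrine cell genes fell in 6 of 14 cases (8 adjusted over the list alone, median -0.33, camera adjusted p = 8.26e-05, adjusted p = 0.308 with an estimated correlation).

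All 13 neurogenic precursor genes fell at P1 by either adjustment, with a median of -0.54 (camera adjusted p = 1.38e-20). Among retinal progenitor genes 5 of 12 fell (7 adjusted over the list alone, median -0.27, camera adjusted p = 6.01e-08). The cell cycle list fell with 5 of 21 genes (5 adjusted over the list alone, median -0.20, camera adjusted p = 0.000518, adjusted p = 0.458 with an estimated correlation). Microglia and macrophage genes rose in 15 of 17 cases (17 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 5.38e-25). C1qa, another complement gene, rose by 0.87 ± 0.08 (adjusted p = 6.59e-07). Targets of p53 rose in 13 of 19 cases (16 adjusted over the list alone, median 0.47, camera adjusted p = 9.7e-15). Among them Eda2r, a receptor of the tumor necrosis factor family, rose by 1.56 ± 0.20 (adjusted p = 3.23e-05). Reactive gliosis genes rose in 5 of 19 cases (6 rose and 1 fell adjusted over the list alone, median 0.28, camera adjusted p = 0.0023). Calls for the lists of rods, of photoreceptors in common, of neurogenic precursors, of progenitors, of microglia, of p53 targets and of gliosis held with an estimated correlation, with adjusted p between 0.000978 and 0.036.

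Genes of tissues outside the retina moved at P1 together with these lists. The widest rises by the naming rule were Mmp13 (7.52 ± 0.45, adjusted p = 3.87e-08), a collagenase of cartilage and bone, Capn11 (5.57 ± 1.15, adjusted p = 0.0146), a calpain protease, and Ibsp (4.60 ± 0.25, adjusted p = 3.42e-09), a protein of bone matrix. Mmp9 (from 1.42 ± 0.54 to 22.7 ± 0.46 CPM), Dmp1 (3.73 ± 0.36) and Acp5 (3.52 ± 0.21), genes of bone and bone resorption, rose as well, with adjusted p of at most 2.1e-06. Among the widest falls were keratins of the hair follicle. Krt71 went from 21.3 ± 0.22 to 0.191 ± 0.19 CPM (-6.72 ± 0.23, adjusted p = 9.39e-13), and Krt25 fell by 5.67 (SE 0.26, adjusted p = 4.87e-11). Krt27 had 299 counts in the controls and 3 in the libraries labelled CKO, a ratio of 88.1 with a 95% counting interval from 29.9 to 430. Tchh, the trichohyalin of the hair root sheath, fell by 2.06 (SE 0.09), Crb1, a polarity protein of photoreceptors and glia, by 1.55 (SE 0.15), and the X-linked Xlr3b by 1.52 (SE 0.20), with adjusted p of at most 6.48e-05. All 5 erythroid genes rose by either adjustment (median 1.59, camera adjusted p = 9.16e-11, adjusted p = 0.0579 with an estimated correlation), with Hba-a2 at 2.05 ± 0.31 (adjusted p = 0.00322) and Hbb-bt at 1.59 ± 0.29 (adjusted p = 0.00816), globin genes whose paralogs may share reads. Vascular genes rose in 3 of 12 cases and 1 fell (7 and 1 adjusted over the list alone, median 0.44, camera adjusted p = 0.000518, adjusted p = 0.345 with an estimated correlation). Genes of muscle and cornea rose in 2 of 9 cases (6 adjusted over the list alone, median 0.78, camera adjusted p = 3.65e-05, adjusted p = 0.352 with an estimated correlation).

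Of the P1 genes named, Capn11 lost its call without any of the 4 P1 libraries in turn (adjusted p from 0.0532 to 0.111). Hbb-bt lost it without control replicate 1, control replicate 2 or CKO replicate 1 (0.0691, 0.0716 and 0.065). Without CKO replicate 1 or 2 the log2 fold change was -8.38 or -6.02 for Krt71 and -10.09 or -5.46 for Krt27, and that of Mmp13 was 8.13 without control replicate 2. Leaving out any P1 library left 1159 to 1276 genes called. A fit without the 4 libraries of P30, chosen after seeing the data, called 5877, and a fit of the 4 P1 libraries alone called 6098.

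The comparison at P7 falls in the first postnatal week of rod and cone maturation. Photoreceptor and bipolar cell genes were lower in the libraries labelled CKO, a group in which Uxt was not lower, and genes of neurogenic precursors were higher. The cone arrestin Arr3 and the cone phosphodiesterase subunit Pde6h fell by 1.76 (SE 0.15, adjusted p = 1.72e-06) and 1.68 (SE 0.12, adjusted p = 1.15e-08). Grm6, the glutamate receptor of ON bipolar cells, fell from 124 ± 1.67 to 68.1 ± 1.20 CPM (-0.87 ± 0.06, adjusted p = 2.07e-08). Crx and Nr2e3 were not called at P7 (-0.05 ± 0.04, adjusted p = 0.542, and 0.07 ± 0.05, adjusted p = 0.508). At this age 1525 genes passed, 585 higher and 940 lower, and 276 of them changed at least 2-fold.

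Among rod genes at P7, 11 of 17 fell (13 adjusted over the list alone, median -0.48, camera adjusted p = 9.75e-13), with Sag at -0.71 ± 0.06 (adjusted p = 2.83e-07). Of the genes common to rods and cones, 11 of 16 fell (12 adjusted over the list alone, median -0.40, camera adjusted p = 1.27e-16). Aipl1, a chaperone of the phosphodiesterase, fell by 0.93 (SE 0.06, adjusted p = 1.92e-09), and Rcvrn, the calcium sensor recoverin, fell by 0.99 (SE 0.07, adjusted p = 1.17e-08). Cone genes fell in 7 of 13 cases (1 rose and 8 fell adjusted over the list alone, median -0.59, camera adjusted p = 1.84e-10, adjusted p = 0.0577 with an estimated correlation). Bipolar cell genes fell in 9 of 15 cases (1 rose and 9 fell adjusted over the list alone, median -0.67, camera adjusted p = 5.92e-08), with Gpr179, a partner of the Grm6 cascade, at -0.70 ± 0.07 (adjusted p = 1.68e-06). Photoreceptor synapse genes fell in 5 of 11 cases (6 adjusted over the list alone, camera adjusted p = 7.65e-06, adjusted p = 0.0927 with an estimated correlation), with a median of -0.22 that became 0.10 when the libraries were scaled on inner retinal neuron genes. Amacrine cell genes fell in 5 of 14 cases (6 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.536 with an estimated correlation), with a median of -0.25 that became 0.07 under that scaling. Ganglion cell genes fell in 2 of 15 cases by either adjustment (camera adjusted p = 0.0236, adjusted p = 0.687 with an estimated correlation), with a median of -0.24 that became 0.08. Under that scaling the medians of rods, of photoreceptors in common, of cones and of bipolar cells became -0.15, -0.08, -0.27 and -0.35.

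Neurogenic precursor genes rose at P7 in 5 of 13 cases by either adjustment (median 0.30, camera adjusted p = 9.7e-06). Progenitor genes rose in 2 of 12 cases (2 rose and 1 fell adjusted over the list alone, median 0.19, camera adjusted p = 0.0138, adjusted p = 0.276 with an estimated correlation). Genes of the unfolded protein response fell in 8 of 11 cases (9 adjusted over the list alone, median -0.38, camera adjusted p = 4.05e-09, adjusted p = 0.0934 with an estimated correlation). Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, fell by 1.24 (SE 0.13, adjusted p = 2.05e-06), and Xbp1, a transcription factor of this response, fell by 0.64 (SE 0.07, adjusted p = 4.41e-06). Secretory gland genes, a list drawn up after seeing the data, fell with them (15 of 15, median -3.69). Glycolysis genes fell in 3 of 13 cases (1 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.0346, adjusted p = 0.293 with an estimated correlation), with a median of -0.19 that became 0.13 when scaled on inner retinal neuron genes. Calls for the lists of rods, of photoreceptors in common, of bipolar cells and of neurogenic precursors held at P7 with an estimated correlation, with adjusted p of 0.0064, 0.012, 0.00667 and 0.0463.

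The widest rises at P7 were Abcd4 (2.58 ± 0.10, adjusted p = 5.25e-10), the X-linked Xlr3b (2.10 ± 0.19, adjusted p = 3.5e-07) and the zinc finger gene Zfp949 (1.97 ± 0.22, adjusted p = 0.000709). R3hdml (1.45 ± 0.15), Robo3 (1.39 ± 0.09), an axon guidance receptor, and Myl10 (1.27 ± 0.18) followed, with adjusted p of at most 0.000106. Among the widest falls, Lipo1, a lipase-like gene, fell from 97.1 ± 0.58 to 4.18 ± 0.64 CPM (-4.53 ± 0.13, adjusted p = 2.41e-13) beside its paralogs Lipo5 (-5.20 ± 0.26) and Lipo4 (-4.26 ± 0.25), whose counts may include shared reads. Mup4, a major urinary protein gene, fell by 4.68 (SE 0.23), Mucl1, a mucin-like gene, by 4.45 (SE 0.19), and Scgb2b33, a secretoglobin, by 4.34 (SE 0.33), with adjusted p of at most 2.83e-07. All 5 erythroid genes fell by either adjustment (median -1.55, camera adjusted p = 1.92e-08, adjusted p = 0.0934 with an estimated correlation). Alas2, the heme synthesis enzyme of red cells, stood at -1.64 ± 0.29 (adjusted p = 0.0101) and Hba-a2 at -1.63 ± 0.30 (adjusted p = 0.0128).

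Camera called 4 lists of tissues around the retina upward at P7, with few of their genes called and no list call kept with an estimated correlation. Pigment epithelium genes rose in 4 of 12 cases (6 adjusted over the list alone, median 0.38, camera adjusted p = 0.000207, adjusted p = 0.0927 with an estimated correlation). The lens list rose as a set (median 0.45, camera adjusted p = 1.62e-05, adjusted p = 0.438 with an estimated correlation), although by edgeR 0 of its 12 genes passed over all genes and 5 passed adjusted over the list alone. Vascular genes rose with 1 of 12 members by either adjustment (median 0.24, camera adjusted p = 0.00494, adjusted p = 0.438 with an estimated correlation). Muscle and cornea genes rose with 1 of 9 by either adjustment (median 0.33, camera adjusted p = 0.00753, adjusted p = 0.577 with an estimated correlation). Alas2 and Hba-a2 lost their calls without any of the 4 P7 libraries in turn (adjusted p from 0.0505 to 0.108). Leaving out any P7 library left 716 to 743 genes called. A fit without the 4 libraries of P30, chosen after seeing the data, called 4366 genes, a fit of the 4 P7 libraries alone called 4169. Scaling on inner retinal neuron genes, also chosen after seeing the data, called 8713 with 95.9% of them higher.

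At P14, around eye opening, genes of rods, of photoreceptors in common and of bipolar cells were lower in the libraries labelled CKO, a group in which Uxt was not lower. Most genes of cones, ganglion, amacrine and horizontal cells fell too, but these list calls were lost (adjusted p = 0.183, 0.145, 0.359 and 0.183 with an estimated correlation). Crx fell from 590 ± 10.6 to 105 ± 0.84 CPM (-2.49 ± 0.04, adjusted p = 1.09e-17), and Nr2e3 fell from 611 ± 8.45 to 84.0 ± 4.71 CPM (-2.86 ± 0.05, adjusted p = 1.09e-17). Gpr179 of ON bipolar cells fell by 2.11 (SE 0.07, adjusted p = 1.37e-14), and Gap43, an axon growth protein of ganglion cells, fell by 2.18 (SE 0.09, adjusted p = 3.26e-13). Most cell cycle genes and immediate early genes were higher, with list calls that were lost as well (adjusted p = 0.441 and 0.562 with an estimated correlation). Fosb, an activity-induced transcription factor, rose by 3.38 ± 0.50 (adjusted p = 0.000349). Genes of secretion and lipid synthesis were among the most abundant of the P14 libraries labelled CKO. Bpifa6, a secreted protein gene, went from 4205 to 15105 CPM, the lipid synthesis genes Elovl5 and Fasn from 3577 to 14461 and from 2200 to 9291 CPM, and Plin2, a lipid droplet gene, from 1665 to 5886 CPM. In all, 12300 genes passed, 6440 higher and 5860 lower, and 4966 changed at least 2-fold, 1878 up and 3088 down.

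All 17 rod genes fell at P14 by either adjustment (median -2.41, camera adjusted p = 7.9e-53). So did all 16 genes common to rods and cones (median -2.28, camera adjusted p = 1.99e-53) and all 11 photoreceptor synapse genes (median -2.19, camera adjusted p = 4.18e-21). Scaled on inner retinal neuron genes, these 3 medians became -0.42, -0.30 and -0.20. Prph2 and Rom1, structural proteins of the outer segment disc, fell by 2.47 (SE 0.05, adjusted p = 5.57e-17) and 2.40 (SE 0.05, adjusted p = 1.29e-16). Stx3, the syntaxin of ribbon synapses, fell by 1.89 (SE 0.05, adjusted p = 7.68e-16), which became 0.10 (adjusted p = 0.299) when scaled on inner retinal neuron genes. Cacna2d4, a calcium channel subunit, fell by 2.29 (SE 0.07, adjusted p = 2.16e-15). Among cone genes 11 of 13 fell and 1 rose (12 and 1 adjusted over the list alone, median -2.80, camera adjusted p = 6.42e-05, adjusted p = 0.183 with an estimated correlation), and the median became -0.83 under that scaling. Cilium genes fell in 13 of 16 cases and 1 rose by either adjustment (camera adjusted p = 2.22e-07, adjusted p = 0.109 with an estimated correlation), with a median of -1.02 that became 0.96 when scaled on inner retinal neuron genes. In that list Cep290 and Bbs1, proteins of the ciliary transition zone and of ciliary transport, fell by 1.79 (SE 0.08, adjusted p = 3.19e-13) and 1.81 (SE 0.09, adjusted p = 2.31e-12). Under that scaling they stood at 0.19 (adjusted p = 0.111) and 0.18 (adjusted p = 0.0904).

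Bipolar cell genes fell at P14 in 14 of 15 cases by either adjustment (median -2.07, camera adjusted p = 9.04e-13), with Grm6 at -1.81 ± 0.06 (adjusted p = 2.41e-14), or 0.17 (adjusted p = 0.159) when scaled on inner retinal neuron genes. That scaling, which rests on the genes of the bipolar, ganglion, amacrine and horizontal cell lists, brought their medians to -0.09, -0.76, -0.14 and -0.50. Ganglion cell genes fell in 14 of 15 cases and 1 rose by either adjustment (median -2.74, camera adjusted p = 1.09e-12, adjusted p = 0.145 with an estimated correlation), with Sncg, a synuclein of ganglion cells, at -2.46 ± 0.10 (adjusted p = 2.52e-13). Amacrine cell genes fell in 10 of 14 cases and 3 rose by either adjustment (median -2.12, camera adjusted p = 0.000388, adjusted p = 0.359 with an estimated correlation). The 3 that rose, Pax6, Tfap2a and Tfap2b, encode transcription factors also made outside amacrine cells. All 5 horizontal cell genes fell by either adjustment (median -2.48, camera adjusted p = 0.0107, adjusted p = 0.183 with an estimated correlation). Progenitor genes fell in 8 of 12 cases and 3 rose by either adjustment (camera adjusted p = 0.0107, adjusted p = 0.218 with an estimated correlation), with a median of -1.49 that became 0.49 when scaled on inner retinal neuron genes. Neurogenic precursor genes fell in 10 of 13 cases by either adjustment (camera adjusted p = 6.42e-05, adjusted p = 0.0518 with an estimated correlation), with a median of -1.50, or -1.56 with genes at 3 counts or fewer placed at their bound, that became 0.41 under that scaling.

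Cell cycle genes rose at P14 in 19 of 21 cases (20 adjusted over the list alone, median 0.79, camera adjusted p = 6.42e-05, adjusted p = 0.441 with an estimated correlation). Immediate early genes rose in 9 of 11 cases by either adjustment (median 1.05, camera adjusted p = 0.00842, adjusted p = 0.562 with an estimated correlation). Reactive gliosis genes rose in 12 of 19 cases and 4 fell by either adjustment (median 0.66, camera adjusted p = 0.0343, adjusted p = 0.14 with an estimated correlation). Genes of the unfolded protein response rose in 6 of 11 cases by either adjustment (median 0.36, camera adjusted p = 0.0476, adjusted p = 0.646 with an estimated correlation). Genes of secretory glands (median 2.26), of lipid synthesis (median 1.88) and of fat cells (median 1.91), lists drawn up after seeing the data, rose at P14 with them. Autophagy genes rose in 9 of 12 cases and 2 fell by either adjustment (median 0.46, camera adjusted p = 0.0476, adjusted p = 0.445 with an estimated correlation). Calls for the lists of rods, of photoreceptors in common, of photoreceptor synapses and of bipolar cells held at P14 with an estimated correlation, with adjusted p of 2.81e-05, 0.000324, 0.00298 and 0.000845.

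Among the widest rises at P14 by the naming rule, Prb1 and Prpmp5, proline-rich proteins of saliva, rose by 3.85 ± 1.18 (adjusted p = 0.024) and 3.35 ± 0.61 (adjusted p = 0.000839). Car4, a carbonic anhydrase, rose by 3.47 ± 0.24 (adjusted p = 3.15e-10), and Scgb2b7, a secretoglobin, by 3.47 ± 0.14 (adjusted p = 1.68e-11). Cyp4a10, a fatty acid hydroxylase, rose from 7.77 ± 0.22 to 81.6 ± 2.04 CPM (3.39 ± 0.13, adjusted p = 9.21e-14). The widest falls were Crhbp (-4.92 ± 0.31), a binding protein of corticotropin-releasing hormone, Optc (-3.73 ± 0.14), the opticin of the vitreous, and Lhx9 (-3.60 ± 0.27), a LIM homeodomain transcription factor. Kcnk9 (-3.49 ± 0.23), a potassium channel, Chst5 (-3.46 ± 0.31), a sulfotransferase, and Tmem72 (-3.40 ± 0.20) followed, and all 6 had adjusted p of at most 2.71e-08. Prb1 lost its call without control replicate 1, control replicate 2 or CKO replicate 2 (adjusted p of 0.105, 0.0789 and 0.0845), and Kcnk9 stood at -4.10 without CKO replicate 2. With library size as the only scaling the median of all genes at P14 was -0.23, and 32.5% of the genes called were higher against 52.4% with TMM. Scaling on inner retinal neuron genes, chosen after seeing the data, put that median at 2.00, with 97.4% higher.

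At P30, in the mature retina, photoreceptor genes were lower in the libraries labelled CKO and genes of gliosis and microglia were higher. Uxt rose in this group. Crx fell from 654 ± 7.77 to 144 ± 2.93 CPM (-2.19 ± 0.04, adjusted p = 8.62e-17), and Pde6b, the rod phosphodiesterase subunit, fell by 2.40 (SE 0.06, adjusted p = 2.67e-16). The cone opsins Opn1sw and Opn1mw fell by 3.66 (SE 0.57, adjusted p = 0.000594) and 2.96 (SE 0.14, adjusted p = 7.19e-12). Opn1sw stood at 18.7 ± 20.9 CPM in the libraries labelled CKO, and its log2 fold change was -2.81 without CKO replicate 1 and -5.89 without CKO replicate 2. Gfap, an intermediate filament of reactive glia, rose from 143 ± 4.06 to 437 ± 72.2 CPM (1.61 ± 0.08, adjusted p = 1.68e-11). At this age 11874 genes passed, 5996 higher and 5878 lower, and 3567 changed at least 2-fold, 1882 up and 1685 down.

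All 17 rod genes fell at P30 by either adjustment (median -2.25, camera adjusted p = 7.97e-84), with Nr2e3 at -2.20 ± 0.05 (adjusted p = 1.9e-16). So did all 16 genes common to rods and cones (median -2.16, camera adjusted p = 1.69e-82), with Prph2 at -2.34 ± 0.05 (adjusted p = 1.1e-16). Among cone genes 12 of 13 fell by either adjustment (median -2.26, camera adjusted p = 9.96e-17), with Pde6h at -2.91 ± 0.11 (adjusted p = 1.7e-13) and the cone transducin Gnat2 at -2.31 ± 0.10 (adjusted p = 6.47e-13). All 11 photoreceptor synapse genes fell by either adjustment (median -1.65, camera adjusted p = 3.03e-27), with Stx3 at -1.59 ± 0.05 (adjusted p = 1.1e-14) and Unc13b, a vesicle priming protein, at -1.70 ± 0.06 (adjusted p = 5.63e-14). Cilium genes fell in 15 of 16 cases by either adjustment (median -0.94, camera adjusted p = 5.48e-11), with Cep290 at -1.77 ± 0.08 (adjusted p = 8.41e-13) and Lca5, a protein of ciliary transport, at -1.62 ± 0.08 (adjusted p = 3.74e-12). Scaled on inner retinal neuron genes, the medians of these 5 lists became -1.54, -1.44, -1.53, -0.95 and -0.24.

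Bipolar cell genes fell at P30 in 13 of 15 cases by either adjustment (camera adjusted p = 2.11e-05), with a median of -0.64 that became 0.07 when scaled on inner retinal neuron genes. Amacrine cell genes fell in 9 of 14 cases and 1 rose by either adjustment (camera adjusted p = 0.00682, adjusted p = 0.44 with an estimated correlation), with a median of -0.46 that became 0.12 under that scaling. Ganglion cell genes fell in 12 of 15 cases and 1 rose by either adjustment (camera adjusted p = 0.0134, adjusted p = 0.49 with an estimated correlation), with a median of -0.65 that became 0.04. All 5 horizontal cell genes fell by either adjustment (median -1.28, camera adjusted p = 0.0281, adjusted p = 0.242 with an estimated correlation), with a median of -0.57 under that scaling. Over genes, the mean log2 fold change of 33 photoreceptor genes minus that of 49 inner retinal neuron genes was -0.54 ± 0.10 at P1, -0.13 ± 0.08 at P7, -0.25 ± 0.17 at P14 and -1.43 ± 0.09 at P30 (SE over genes, which are not independent replicates).

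**Figure D2:**
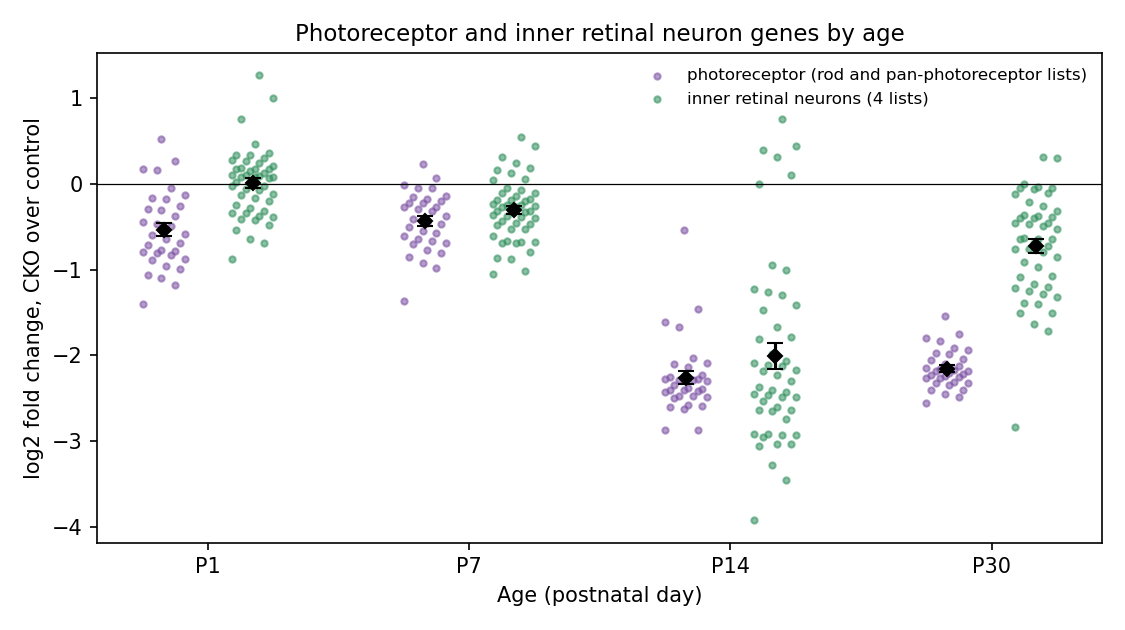
Log2 fold change of the libraries labelled CKO over controls (vertical axis) by age in postnatal days (horizontal axis) for 33 photoreceptor genes and 49 inner retinal neuron genes, with 1 point per gene and a bar at each mean. The means at P14 are -2.26 and -2.01 and at P30 -2.15 and -0.73, all scaled by TMM. Scaling on the inner retinal neuron genes raises all these values at P7, P14 and P30 and turns part of them positive.

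All 19 reactive gliosis genes rose at P30 by either adjustment (median 0.97, camera adjusted p = 8.57e-13), with Nes, the intermediate filament nestin, at 1.62 ± 0.08 (adjusted p = 3.44e-12). Microglia and macrophage genes rose in 16 of 17 cases by either adjustment (median 0.91, camera adjusted p = 4.86e-07). Interferon response genes rose in 12 of 15 by either adjustment (median 0.72, camera adjusted p = 0.0107, adjusted p = 0.465 with an estimated correlation). All 15 nuclear genes of oxidative phosphorylation rose by either adjustment (median 1.02, camera adjusted p = 4.67e-09, adjusted p = 0.274 with an estimated correlation). So did all 10 mitochondrially encoded genes (median 1.18, camera adjusted p = 6.58e-05, adjusted p = 0.416 with an estimated correlation). Glycolysis genes fell in 8 of 13 cases and 2 rose by either adjustment (camera adjusted p = 0.0132, adjusted p = 0.213 with an estimated correlation), with a median of -0.45 that became 0.27 when scaled on inner retinal neuron genes. Immediate early genes rose in 9 of 11 cases and 1 fell by either adjustment (median 1.13, camera adjusted p = 0.0149, adjusted p = 0.465 with an estimated correlation).

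Genes of tissues outside the neural retina moved at P30 with these lists. Vascular genes rose in 11 of 12 cases by either adjustment (median 1.22, camera adjusted p = 2.21e-05, adjusted p = 0.24 with an estimated correlation). Pigment epithelium genes rose in 8 of 12 by either adjustment (median 0.91, camera adjusted p = 0.000117, adjusted p = 0.0448 with an estimated correlation). Lens genes fell in 10 of 12 cases (11 adjusted over the list alone, median -0.75, camera adjusted p = 0.00176, adjusted p = 0.465 with an estimated correlation). Muscle and cornea genes rose in 8 of 9 cases by either adjustment (median 3.02, camera adjusted p = 1.5e-09, adjusted p = 0.173 with an estimated correlation). Myh13, a myosin of eye muscle, went from 8.70 ± 0.60 to 984 ± 396 CPM (6.82 ± 0.31, adjusted p = 1.11e-07). Chrnd, an acetylcholine receptor subunit of muscle, had 2 counts in the controls and 214 in the libraries labelled CKO, a ratio of 86.9 with a 95% counting interval from 23.8 to 722. Genes of fat cells followed: Pck1 (5.51 ± 0.14), Adipoq (5.25 ± 0.28), Cidec (5.05 ± 0.23) and Plin1 (4.82 ± 0.29), with adjusted p of at most 3.57e-10. Without control replicate 1 Chrnd stood at 9.60, Adipoq at 6.36 and Plin1 at 6.11, and without control replicate 2 Chrnd stood at 5.43 and Plin1 at 4.23. Without CKO replicate 2 Chrnd stood at 5.37. Besides the cone genes, the widest falls were Slc17a4 (-3.20 ± 0.43), a phosphate transporter, Kcne2 (-3.07 ± 0.40), a potassium channel subunit, and Sh2d1a (-2.86 ± 0.34), a signalling adaptor, with adjusted p of at most 5.89e-05. Kcne2 stood at -2.35 without CKO replicate 1 and -4.54 without CKO replicate 2. Calls for the lists of rods, of photoreceptors in common, of cones, of photoreceptor synapses, of cilia, of bipolar cells, of gliosis, of microglia and of pigment epithelium held at P30 with an estimated correlation, with adjusted p between 8.37e-06 and 0.0448. Scaling on inner retinal neuron genes, chosen after seeing the data, put the median of all genes at 0.70 at P30 and 0.33 at P7. At P30, 91.9% of calls were then higher against 50.5%.

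**Figure D3:**
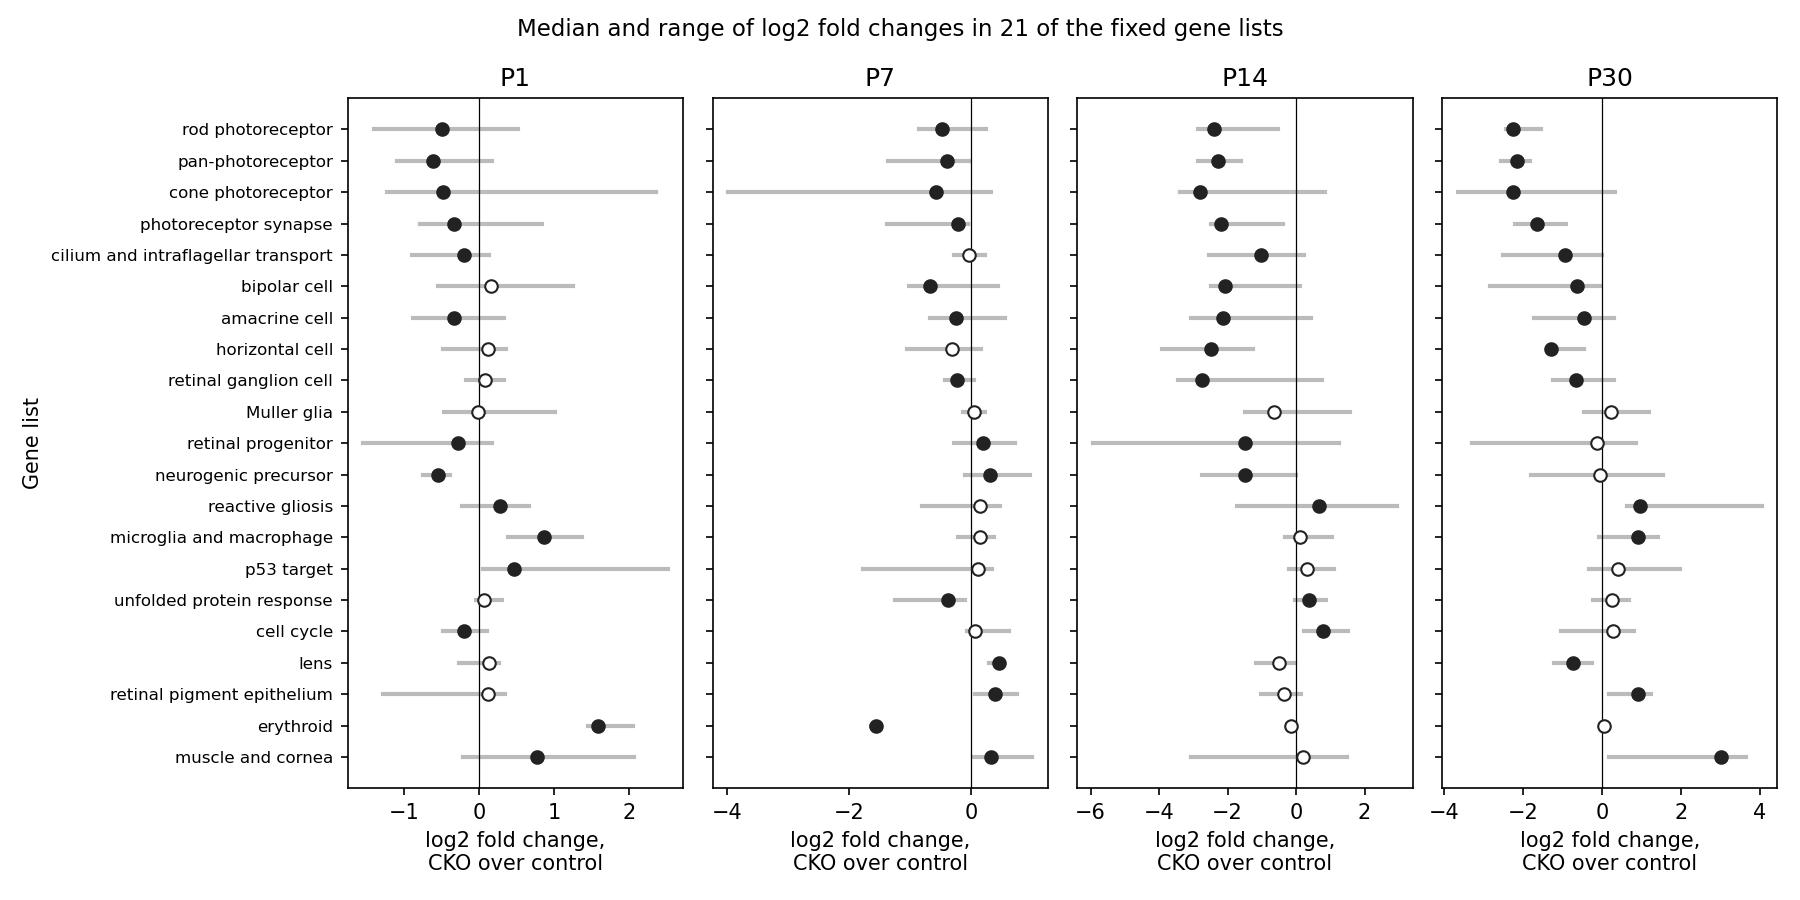
Median (point) and range (line) of the log2 fold changes of the libraries labelled CKO over controls (horizontal axis) in 21 of the fixed gene lists (vertical axis), with 1 panel per age. Rod medians are -0.50, -0.48, -2.41 and -2.25 from P1 to P30, all scaled by TMM. With library size alone the medians of the lists of microglia and of muscle and cornea change sign at P14 and that of the erythroid list at P30. Scaling on inner retinal neuron genes turns those of several neuronal, glial and other lists positive at P7, P14 or P30.

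The differences between labels were compared between successive ages by interaction tests. From P1 to P7, the difference between labels moved for 1514 genes, 753 upward and 761 downward, with Uxt among them (1.04, adjusted p = 0.0181). With scaling on inner retinal neuron genes 4118 moved, 3902 upward and 216 downward. Neurogenic precursor genes, which fell at P1, moved upward in 12 of 13 cases (13 adjusted over the list alone, median 0.85, camera adjusted p = 1.66e-31). Microglia genes moved downward in 10 of 17 (13 adjusted over the list alone, median -0.74, camera adjusted p = 3.08e-14). Erythroid genes reversed, with all 5 moving downward by either adjustment (median -3.12, camera adjusted p = 5.32e-29). Bipolar cell genes moved downward in 4 of 15 cases (6 adjusted over the list alone, median -0.76, camera adjusted p = 9.07e-05). Progenitor genes moved upward in 4 of 12 cases (8 adjusted over the list alone, median 0.49, camera adjusted p = 2.48e-12). Targets of p53 moved downward in 6 of 19 (13 adjusted over the list alone, median -0.38, camera adjusted p = 1.02e-07). These 6 calls held with an estimated correlation, of 13 lists called. The rod list had a median of -0.0051 but a mean of 0.13 and a test upward (camera adjusted p = 0.00128, adjusted p = 0.068 with an estimated correlation), with 6 of 17 genes moving upward and 2 downward (7 and 2 adjusted over the list alone). Leaving out any library of P1 or P7 left 794 to 923 genes.

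From P7 to P14 the difference between labels moved for 10242 genes, 5034 upward and 5208 downward. With scaling on inner retinal neuron genes 16187 moved, 15675 upward and 512 downward, and the list moves were not tested under that scaling. The groups differed in sex at P7 and not at P14, so this comparison holds sex and age together. Rod genes moved downward in 16 of 17 cases (median -1.81, camera adjusted p = 3.77e-32), genes common to rods and cones in 15 of 16 (median -1.87, camera adjusted p = 9.53e-32), and photoreceptor synapse genes in 10 of 11 (median -1.80, camera adjusted p = 9.82e-14), with the same counts adjusted over the list alone. Bipolar cell genes moved downward in 14 of 15 cases and 1 upward by either adjustment (median -1.46, camera adjusted p = 3.55e-06). Neurogenic precursor genes moved downward in 12 of 13 cases by either adjustment (median -1.81, camera adjusted p = 2.39e-07). These 5 of 16 calls held with an estimated correlation. From P30 against P14, 9500 genes differed, 5026 upward and 4474 downward. With scaling on inner retinal neuron genes 14322 differed, 670 upward and 13652 downward. Bipolar cell genes moved upward in 12 of 15 cases and 1 downward by either adjustment (median 0.95, camera adjusted p = 7.63e-06). This was the only call of 14 that held with an estimated correlation (adjusted p = 0.04). Scaling on inner retinal neuron genes raised the bipolar median more at P14 (from -2.07 to -0.09) than at P30 (from -0.64 to 0.07). That scaling rests partly on the bipolar genes themselves and pulls their median toward 0 by construction. These values therefore do not decide how far the move depends on the scaling. The move of this list was not tested under that scaling. The rod list did not pass there (median 0.16, camera adjusted p = 0.781). Ganglion cell genes moved upward in 14 of 15 cases and 1 downward by either adjustment (median 1.98, camera adjusted p = 8.14e-11, adjusted p = 0.209 with an estimated correlation).

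Genes called at successive ages were compared by direction. Between P1 and P7, 198 genes were called higher at both ages and 116 lower at both, against 35.7 and 61.7 expected by chance. A further 197 were called in opposite directions against 95.9, with a Spearman correlation of log2 fold changes across genes of 0.08. By Xist and Ddx3y the controls were male and the libraries labelled CKO female at both ages. Genes that differ by sex may thus be among the shared calls. Between P7 and P14, 127 genes were called higher at both ages, fewer than the 178 expected by chance, and 348 lower at both against 261. Another 741 were called in opposite directions against 449, with a correlation of -0.02. Between P14 and P30, 6628 genes were called in the same direction, 3225 higher and 3403 lower, against 3460 expected, and 1375 in opposite directions against 3457, with a correlation of 0.47. The expected numbers take every gene as equally likely to be called. Genes are not independent replicates, and 1290 and 1548 genes overlapped in the same direction for the earlier pairs when each age was fitted alone.

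The control libraries give the course with age against which these differences stand. RNA of other tissues changed in them as well. Col1a1 stood at 6887 CPM in the P14 controls and 279 CPM in the P30 controls, and Krt12 of corneal epithelium at 97.2 and 1722 CPM. Steps between ages may thus hold maturation and tissue content together. Crx rose by 1.88 ± 0.04 from P1 to P7 (adjusted p = 2.54e-17), stood at 0.02 ± 0.04 from P7 to P14 (adjusted p = 0.704), and rose by 0.15 ± 0.04 to P30 (adjusted p = 0.00454, or 0.0539 without P14 control replicate 1). The step from P7 to P14 became a fall with library size alone (-0.16, adjusted p = 0.0122) and when scaled on inner retinal neuron genes (-0.30, adjusted p = 0.00704). Under the latter scaling the step to P30 became -0.21 (adjusted p = 0.0341). Grm6 rose by 9.08 ± 0.14 and 0.85 ± 0.06 and then fell by 0.73 (SE 0.06), with adjusted p of at most 7.15e-09. Glul, the glutamine synthetase of Muller glia, fell by 0.80 (SE 0.05) and then rose by 1.14 ± 0.05 and 1.35 ± 0.05, with adjusted p of at most 1.57e-10. Mki67, a proliferation marker, fell by 2.10 (SE 0.25, adjusted p = 0.000103), 1.20 (SE 0.26, adjusted p = 0.00666) and 1.07 (SE 0.29, adjusted p = 0.0133). Pou4f2, a transcription factor of ganglion cells, fell by 1.46 (SE 0.17, adjusted p = 5.68e-07) and 0.51 (SE 0.19, adjusted p = 0.048) and rose by 0.52 ± 0.20 (adjusted p = 0.0329). Pou4f2 lost its P14 and P30 calls without any library involved (adjusted p from 0.0864 to 0.186), and Mki67 lost its P30 call without P14 control replicate 1 or P30 control replicate 2 (0.056 and 0.0867).

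Rod genes rose in the controls in 17 of 17 cases from P1 to P7 (median 3.98, camera adjusted p = 1.04e-105), in 15 of 17 to P14 (median 1.32, camera adjusted p = 4.74e-55) and in 15 of 17 with 2 falls to P30 (median 1.02, camera adjusted p = 7.51e-17), with the same counts adjusted over the list alone. Bipolar cell genes rose in 14 of 15 cases and 1 fell from P1 to P7 by either adjustment (median 1.53, camera adjusted p = 1.07e-15). Neurogenic precursor genes fell in 10 of 13 cases and 3 rose by either adjustment (median -1.91, camera adjusted p = 4.33e-19). All 21 cell cycle genes fell from P1 to P7 by either adjustment (median -1.68, camera adjusted p = 9.05e-28). These calls held with an estimated correlation. The numbers of genes called were 10502 from P1 to P7 (5394 higher and 5108 lower), 7375 from P7 to P14 (3941 and 3434) and 11193 from P14 to P30 (5325 and 5868). The sex of the controls, by Xist and Ddx3y, differed between P7 and P14 and between P14 and P30, so the last 2 comparisons hold sex and age together.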

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

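The tests of explanations for the 3 patterns weighed here were chosen only after the results were seen, whereas the tests of differences between ages were planned.

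The lists of rod genes and of genes common to rods and cones were lower in the libraries labelled CKO at all 4 ages, although at P7 Crx (-0.05) and Nr2e3 (0.07) were not called. A lower share of retina would lower photoreceptor and inner retinal neuron genes alike. The tables argue against it as the whole cause at P30, where their difference was -1.43 ± 0.09 (SE over genes). At P1 the difference was -0.54 ± 0.10, but the inner genes include bipolar cell genes, which rose from P1 to P7 in the controls. Amacrine cell, progenitor and neurogenic precursor genes also fell at P1 (medians of -0.33, -0.27 and -0.54). Ganglion and horizontal cell genes had medians of 0.08 and 0.13, so the argument at P1 rests on these lists alone. At P7 the difference was -0.13 ± 0.08, as a lower share would give. The 13 neurogenic precursor genes (mean 0.34 ± 0.08) argue against a lower share only if specific to retina, which was not tested. At P14 the difference was -0.25 ± 0.17, so a lower share of retina may account for most of the fall, although the per-library mean log2 CPM of photoreceptor minus inner genes went from 3.93 ± 0.01 to 3.61 ± 0.07 (SD, n = 2). Genes of secretory glands (median 2.26) and of lipid synthesis (median 1.88) rose at that age, with Bpifa6 at 4205 and 15105 CPM in controls and libraries labelled CKO. A less mature retina at P7 stays open, since across 143 genes the log2 fold changes correlated with control maturation at a Spearman coefficient of -0.57. This rests on the 89 genes that rise with maturation (median -0.31), as the 54 that fall with it had a median of -0.00021. The coefficient was 0.09 at P1, -0.18 at P14 and -0.49 at P30, so a value near that of P7 also arose in mature retina and does not by itself mark a less mature one. A sex difference cannot be told apart from the label at P1 and P7, where the groups differ in both. Between these ages the photoreceptor lists moved by a mean of 0.10 ± 0.11 (SE over genes), but single genes moved both ways. Crx and Nr2e3 moved by 0.74 and 1.06, and Aipl1 by -0.34. An effect of Uxt loss stays open. At P1, where Uxt was lower, the groups also differ in sex, and at P7, P14 and P30 Uxt was not lower, so it was not tested.

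Uxt was not lower in the libraries labelled CKO at P7, P14 and P30. Labels swapped between control and CKO at P30 would need low Abcd4 in the libraries labelled CKO. The lowest of these at P30, 86.0 CPM, lay above the highest P30 control, 29.8 CPM. This argues against a swap only if Abcd4 follows the genotype, which cannot be told from sex at P1 and P7. At P14 Abcd4 was as high in the controls (192 to 197 CPM) as in the libraries labelled CKO, so it cannot decide. Between P14 and P30, 6628 genes were called in the same direction against 3460 expected, and the rod medians were -2.41 and -2.25. This speaks against a swap at P14 alone only if the genotypes differ alike at both ages, which was not tested. A Cre transgene in the P14 controls stays open and was not tested. Transcripts without exon 3 could still be counted, since this exon holds 9.37% of the transcript. Its loss alone would change a count by -0.14 on the log2 scale, less than the SE of the fit. This explanation therefore cannot be told apart from intact Uxt in counts per gene. Neither by itself gives the rise of Uxt at P30, from 4.68 ± 0.33 to 6.73 ± 0.40 CPM. Signal from cells outside the Cre lineage, which the design leaves intact, stays open and was not tested.

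Genes of tissues outside the retina differed between the groups at every age. At P30 different amounts of muscle may have entered the libraries, since the median log2 ratio of 12 muscle genes between the libraries labelled CKO was 0.996, above the central 95% of all genes (-0.65 to 0.78), with all 12 higher in replicate 2. For erythroid genes, a sex difference common to P1 and P7 is argued against by a reversal of -3.25 ± 0.12 between these ages. For gland, hair follicle and bone genes at P1, P7 and P14 the largest median log2 ratio between the 2 libraries of a group was 0.13, which decides nothing, since the labels do not say that the 2 libraries come from separate tissue. Bone genes (median 2.99 at P1) and secretory gland genes (median -3.69 at P7) moved as lists, as different amounts of tissue would give. These lists were drawn up after seeing the data, and the tissue content of the libraries was not measured. Different amounts of these tissues therefore stay open. No biological explanation was tested for this pattern.

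The interaction tests found that the difference between labels changed for 1514 genes from P1 to P7, 10242 from P7 to P14 and 9500 from P14 to P30. Since the groups differed in sex at P7 and not at P14, the step from P7 to P14 holds sex and age together. From P1 to P7 the log2 fold change of named genes moved by 1.04 for Uxt, 7.12 for Krt71, 6.16 for Krt25, 2.60 for Tchh, 1.26 for Crb1, 3.62 for Xlr3b, 0.85 for Neurod1, 0.73 for Neurog2, 0.74 for Crx, 0.60 for Pdc, 1.06 for Nr2e3, 0.70 for Sag, 1.92 for R3hdml and 2.44 for Robo3. Over the same ages it moved by -7.78 for Mmp13, -7.52 for Capn11, -5.25 for Ibsp, -3.82 for Mmp9, -4.50 for Dmp1, -3.32 for Acp5, -0.86 for C1qc, -0.76 for C1qa, -2.19 for Pmaip1, -1.29 for Eda2r, -3.68 for Hba-a2, -3.12 for Hbb-bt, -0.34 for Aipl1, -0.93 for Pde6h, -1.20 for Sdf2l1, -0.95 for Xbp1 and -3.34 for Alas2. Capn11 lost this call without control replicate 1, control replicate 2 or CKO replicate 2 of P1 or without any library of P7 (adjusted p from 0.0529 to 0.0845). Without P1 CKO replicate 1 or 2 Krt71 moved by 8.77 or 6.41, and Mmp13 moved by -8.39 without P1 control replicate 2 and by -8.38 without P7 CKO replicate 2. Fitted values of 8.49 for Krt81, 7.26 for Krtap11-1, 6.78 for Krt27 and -9.35 for Scgb2b2 depend on the prior count, since a P1 group held 0 to 3 counts. Krt81 stood at 1.33 and 0 CPM in controls and libraries labelled CKO at P1 and at 5.29 and 9.59 CPM at P7, Krtap11-1 at 0.587 and 0 and at 3.49 and 6.02 CPM, and Scgb2b2 at 0 and 0.389 and at 785 and 70.7 CPM. Medians of lists moved by -0.74 for microglia and macrophage genes, 0.85 for neurogenic precursor genes, -0.38 for p53 targets, -3.12 for erythroid genes, -0.49 for the unfolded protein response (camera adjusted p = 7.66e-12, adjusted p = 0.0659 with an estimated correlation) and -0.76 for bipolar cell genes. The rod list moved by a median of -0.0051, although its test was upward (camera adjusted p = 0.00128, adjusted p = 0.068 with an estimated correlation).

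From P7 to P14 the log2 fold change moved by 3.74 for Car4, 7.30 for Scgb2b7, 3.18 for Cyp4a10, 3.53 for Fosb, 6.19 for Prpmp5, 8.44 for Lipo4 and 7.51 for Lipo5, the last 2 being paralogs with possibly shared reads, for which no test such as those giving -3.25 and 0.13 was made. It moved by -4.42 for Crhbp, -3.76 for Optc, -3.89 for Lhx9, -2.70 for Kcnk9, -3.41 for Chst5, -3.94 for Tmem72, -2.43 for Crx, -2.09 for Prph2, -2.93 for Nr2e3, -2.26 for Rom1, -1.66 for Stx3, -1.86 for Cacna2d4, -1.41 for Gpr179, -0.94 for Grm6, -2.14 for Sncg, -2.13 for Gap43, -1.75 for Cep290, -1.74 for Bbs1 and -4.77 for Arid3c. AA623943, with a fitted value of -5.22 that depends on the prior count, stood at 18.6 and 17.1 CPM in controls and libraries labelled CKO at P7 and at 1.63 and 0.0335 CPM at P14. It moved by -4.31 without P14 CKO replicate 1 and by -7.80 without P14 CKO replicate 2, and Lipo4 moved by 9.42 without P14 control replicate 2. Medians of lists moved by -1.87 for genes common to rods and cones, -1.81 for rod genes, -1.80 for photoreceptor synapse genes and -1.46 for bipolar cell genes. Those of ganglion cell genes moved by -2.50 (camera adjusted p = 5.78e-11, adjusted p = 0.189 with an estimated correlation) and those of cilium genes by -0.94 (camera adjusted p = 1.88e-06, adjusted p = 0.147 with an estimated correlation).

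From P14 to P30 the log2 fold change moved by 4.94 for Myh13, 3.36 for Pck1, 3.24 for Adipoq, 2.94 for Cidec, 3.38 for Plin1, 0.66 for Nr2e3, 0.30 for Crx, 0.30 for Stx3, 1.32 for Nes and 2.26 for Gfap, and by -1.30 for Unc13b, -5.44 for Capn11 and -4.63 for Hdc. Capn11 lost this call without P14 control replicate 1, P14 control replicate 2, P14 CKO replicate 1, P30 CKO replicate 1 or P30 CKO replicate 2 (adjusted p from 0.0511 to 0.0736). It moved by -6.26 without P14 control replicate 2, by -6.39 without P30 control replicate 1 and by -2.33 without P30 control replicate 2. Fitted values of 7.82 for Avp, 7.54 for Gcg, 5.54 for Chrnd and -5.13 for Prss16 depend on the prior count, since a P30 group held 0 to 3 counts, and Prss16 lost its call without P30 control replicate 2 or P30 CKO replicate 2 (0.108 and 0.0527). Avp stood at 6.31 and 1.14 CPM in controls and libraries labelled CKO at P14 and at 0.0618 and 2.77 ± 2.95 CPM at P30. Gcg stood at 5.10 and 0.504 and at 0.0289 and 0.666 ± 0.363 CPM, Chrnd at 0.786 and 1.31 and at 0.0577 and 5.06 ± 3.40 CPM, and Prss16 at 2.17 and 5.31 and at 0.0907 and 0 CPM. The sizes depended on single libraries of P30. Without control replicate 1 or 2 the move was 6.84 or 11.11 for Avp, 9.97 or 6.72 for Gcg and 8.82 or 4.65 for Chrnd. Without CKO replicate 1 or 2 it was 5.84 or 8.65 for Avp, and without CKO replicate 2 it was 6.82 for Gcg and 4.59 for Chrnd. The median of the reactive gliosis list moved by 0.40 (camera adjusted p = 0.00171, adjusted p = 0.0511 with an estimated correlation).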

How the results depend on the processing

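Scaling on inner retinal neuron genes and the fit without P30 were chosen after seeing the data, and the other alternatives were planned. Of 131 named results, 131 kept direction and side of the threshold with RLE, 130 with library size alone, 130 with no filter, 129 of 129 with the stricter filter, 129 of 130 with DESeq2, 123 with the replicate block, 122 with scaling on inner retinal neuron genes, 96 of 96 without P30, and 552 of 596 values with a library left out. A group left with 1 library is assumed to vary like the others. Uxt is not among these named results. It had 62 to 156 counts per library, and its calls changed in several of the settings given below. Except where a construction is named, the cause was not tested.

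Replicate numbers do not pair the samples: deviations within groups correlated at -0.022, 0.014, -0.032 and -0.024 from P1 to P30. With a replicate block 2367, 1350, 12024 and 11603 genes were called from P1 to P30, 1225, 10003 and 9206 in the interactions and 10320, 7086 and 10928 in the controls, and Hbb-bt (P1), Alas2 and Hba-a2 (P7), Prb1 (P14) and the later steps of Mki67 and Pou4f2 in controls lost their calls.

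Leaving out each library of the ages involved gave 1159 to 1276 genes at P1, 716 to 743 at P7 and 794 to 923 for P7 against P1. Uxt ranged from -1.05 to -0.63 at P1, from 0.13 to 0.62 at P14 and from 0.50 to 0.63 at P30. Crx from P7 to P14 in controls ranged from -0.0095 (without P14 control replicate 2) to 0.028.

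Fitted on the 4 libraries of an age, 6098 genes were called at P1 and 4169 at P7, and the overlap in the same direction was 1290 for P1 and P7 and 1548 for P7 and P14. Without P30, whose replicates differ most, 5877 genes were called at P1, 4366 at P7 and 4546 for P7 against P1, and Uxt at P14 was 0.36 (adjusted p = 0.0333).

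Scaled on inner retinal neuron genes, which moves every log2 fold change by its shift, 1140 genes were called at P1, 8713 at P7, 4118 for P7 against P1, 16187 for P14 against P7 and 14322 for P30 against P14. Uxt became 0.55 (adjusted p = 0.0349) at P7 and 2.29 (adjusted p = 3.14e-09) at P14, and at P14 Stx3 became 0.10, Grm6 0.17, Cep290 0.19 and Bbs1 0.18. Crx in controls became -0.30 (adjusted p = 0.00704) from P7 to P14 and -0.21 (adjusted p = 0.0341) from P14 to P30, and -0.16 (adjusted p = 0.0122) from P7 to P14 with library size alone.

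Lists called fell to 7, 4, 4 and 9 from P1 to P30 with an estimated correlation, and at P14 were 30 with fry, which does not compare a list with other genes, and 27 with no filter.

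The Y-linked covariate nearly coincides with the label at P1 and P7, so this fit extrapolates from small deviations within groups. By edgeR it called 0 genes at P1 (726 at an unadjusted p under 0.05, and 2154 by DESeq2 without the covariate), 0 at P7 (735 and 1215), 4619 at P30, 779 for P7 against P1, 0 for P14 against P7 (913 and 9051), and in controls 0 from P7 to P14 (787 and 6079) and 0 from P14 to P30 (807 and 9694). It called 5 lists at P1 and 5 at P7. Of the named results other than Uxt it kept 63, with 38 losing their call and 30 reversed. Uxt became -8.93 at P1, -7.73 at P7 and 0.17 at P30. At P1 the reversed genes were Mmp13 at -34.4, Acp5 at -13.02, Krt25 at 2.25, C1qa at -1.20, Neurod1 at 1.92, Pmaip1 at -25.1, Eda2r at -12.01, Pdc at 3.29, Nr2e3 at 0.23 and Sag at 1.93. At P7 they were Xlr3b at -2.24, Robo3 at -10.34, Lipo5 at 14.88, Mup4 at 14.44, Mucl1 at 6.98, Scgb2b33 at 22.81, Lipo4 at 3.98, Aipl1 at 3.04, Rcvrn at 1.08, Sag at 2.56, Pde6h at 5.14, Arr3 at 2.75, Xbp1 at 2.18, Alas2 at 18.9, Hba-a2 at 18.98 and Grm6 at 0.47. The move from P7 to P14 became -12.31 for Lipo5 and -2.81 for Scgb2b7, and control changes from P14 to P30 became -1.42 for Glul and 13.37 for Mki67.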

Other observations

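A small set of genes was called in the same direction at all 4 ages, far more than the 4.77 lower and 3.10 higher expected by chance. The 90 genes lower in the libraries labelled CKO at P1, P7, P14 and P30 included the photoreceptor genes Rp1, Sag, Pdc, Pde6b, Gnat2, Pde6h, Grk1, Rbp3, Rcvrn, Aipl1, Prph2 and Tulp1, the cilium genes Lca5, Rpgr and Pcare, and the synaptic genes Cacna2d4 and Stx3. The 41 genes higher at all ages included Cd34, a marker of endothelium, Col4a1 and Col4a2, collagens of basement membranes, Acta2 and Myh11, contractile proteins of smooth muscle, and Gpnmb, a glycoprotein of macrophages and melanocytes. The genes named here were picked after seeing the lists, without a test of what they have in common. These counts share a dispersion estimate, and genes are not independent replicates.

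Uxt belongs to the family of prefoldin-like proteins. By camera the prefoldin and R2TP list, which does not hold Uxt, was not called at any age. Its medians were 0.03 at P1 (camera adjusted p = 0.984), 0.04 at P7 (0.543), 0.25 at P14 (0.321, and -0.00099 with library size alone) and 0.08 at P30 (0.781). At P14, 9 of its 14 genes rose and 1 fell (10 and 1 adjusted over the list alone), and fry called the list (adjusted p = 0.000465). Scaled on inner retinal neuron genes, its medians became 2.24 at P14 and 0.80 at P30. The CCT chaperonin list was not called by camera either and was called by fry at P14 (adjusted p = 0.00553), with medians of 0.04, 0.03 (-0.01 with library size alone), 0.17 (-0.08 with library size alone) and 0.06, of which the last 2 became 2.16 and 0.78 when scaled on inner retinal neuron genes. Splicing factor genes had medians of -0.03, 0.05, 0.08 (-0.17 with library size alone) and -0.19 (0.53 when scaled on inner retinal neuron genes). Camera did not call this list at any age, and fry called it at P14 (adjusted p = 0.0056) and P30 (adjusted p = 5.53e-05). Nor did camera call the lists of cytosolic heat shock, cell death effectors, the integrated stress response and NF-kB targets at any age. Fry called cytosolic heat shock at P14, NF-kB targets at P30, and cell death effectors and the integrated stress response at P1, P14 and P30, with adjusted p of at most 0.0392. The Muller glia list was not called by camera at any age and was called by fry at P14 (adjusted p = 0.0232) and P30 (adjusted p = 0.01). Its medians were -0.02, 0.04, -0.65 and 0.22, of which that at P14 became 1.33 when scaled on inner retinal neuron genes.

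The 7 lists of other tissues or functions were drawn up after seeing which genes changed most, so their counts are no independent evidence, and the members were not tested as sets. At P1 all 10 bone genes rose (median 2.99) and all 7 hair follicle genes fell (median -3.78, or -4.07 with genes at 3 counts or fewer placed at their bound). At P7 all 15 secretory gland genes fell (median -3.69) and 6 of 7 hair follicle genes rose (median 0.43). At P14, 14 of 15 secretory gland genes (median 2.26), all 9 lipid synthesis genes (median 1.88), all 7 hair follicle genes (median 2.82) and 6 of 8 adipocyte genes (median 1.91) rose, while 6 of 7 connective tissue genes fell, with a median of -0.45 that became 1.53 when scaled on inner retinal neuron genes. At P30 all 12 skeletal muscle genes (median 3.50), all 8 adipocyte genes (median 4.34) and all 7 connective tissue genes (median 0.93) rose. Scd1, an enzyme of fatty acid synthesis, stood at 2196 ± 8.37 CPM in the P14 controls and 10338 ± 116 CPM in the P14 libraries labelled CKO, and Krt12, a keratin of corneal epithelium, at 97.2 ± 1.37 and 11.6 ± 0.81 CPM.

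Zfp949 resembled Abcd4 in its course. It stood in controls and libraries labelled CKO at 19.1 and 72.1 CPM at P1, 22.6 and 88.5 CPM at P7, 120 and 136 CPM at P14, and 29.9 and 71.4 CPM at P30.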
